A study of Mus musculus with 8 samples.

How the data were processed

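Hypothalamic tissue of mouse fetuses at embryonic day 14.5 was dissociated with papain, per the labels. Cells positive for red fluorescent protein (RFP) were sorted by flow cytometry after exclusion of dead cells with propidium iodide. RFP came from Ai9, a reporter allele switched on by Cre recombinase, so the sorted cells had expressed Ptf1a-cre or descended from cells that had. The labels give the strain as C57BL/6. Libraries were made from 10 ng of total RNA with the SMARTer Stranded Total RNA-Seq kit for mammalian samples of Pico input and sequenced as paired-end reads of 36 bases on a NextSeq500.

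The deposited tables give read counts for 51826 Ensembl genes per library. The counts are whole numbers of total and uniquely mapped reads over exons, the whole gene, introns and exon-exon junctions, per the file headers. An expression value deposited by the authors in the same tables is also a count. It equalled the unique exon reads plus the difference between total and unique exon-exon reads for all 51826 genes in each library. The authors also gave RPKM, which was built from total exon reads for every gene with at least 20 reads (tolerance 1e-06). TPM values deposited by the authors summed to 1000000 in each library. Genome builds are given as GRCm38 and mm10 by the submitters' processing notes. The mapping and counting software, and whether strand was used in counting, are not given in the sources used here. Values of antisense genes, and of genes that share sequence with paralogs or pseudogenes, are uncertain for that reason. The tables carry no exon length for 18706 genes.

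Libraries were grouped by the genotype labels into 4 heterozygous (Ptf1a cre/+, libraries 1 to 4) and 4 homozygous (Ptf1a cre/cre, libraries 9 to 12) libraries. Labels do not say whether each library came from a separate embryo. The p-values therefore measure the spread between these libraries, which may be partly technical. Library numbers are shared by no heterozygous and homozygous library, so no block was fitted.

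The main comparison, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Total exon reads, the column from which the authors' RPKM is built, were tested in edgeR 4.0.16 under R 4.3.3. The low-count filter was filterByExpr with default settings. Normalization used TMM, and the quasi-likelihood F test compared homozygous with heterozygous libraries. A positive log2 fold change means a higher level in homozygous libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The standard error (SE) of a log2 fold change was approximated as its size divided by the square root of the F statistic. Levels are counts per 1000000 reads (CPM) on TMM-scaled library sizes, given as mean ± SD of 4 libraries per genotype. Gene-wise permutation tests and measures of library quality used exact two-sided permutation of 4 against 4 libraries, whose 35 splits allow no p below 0.0286. The gene-wise tests added 1 CPM before the log2 scale. A gene with 0 reads was given an upper limit of 3 reads. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

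The 31 gene lists covered the PTF1 complex, genes downstream of Ptf1a in other tissues, GABA and glycine transmission, glutamate transmission, transcription factors of inhibitory and of excitatory neurons, hypothalamic neuropeptides, monoamine neurons, sex steroid and reproductive signalling, and regional hypothalamic transcription factors. Further lists covered neural progenitors, cell cycle, pan-neuronal genes, synaptic receptors and channels, axon guidance, Notch signalling, Sonic hedgehog and Wnt signalling, apoptosis and p53, and immediate-early and dissociation genes. Markers of other cells or regions made up the rest: astrocytes and tanycytes, oligodendrocyte lineage, myeloid cells, endothelium, mesenchyme and pericytes, erythroid cells, pituitary, telencephalon, thalamus and prethalamus, hindbrain and spinal cord, retina and eye, and the Y chromosome. Each list with at least 3 tested members entered limma camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2). Camera with an estimated correlation and fry were run beside it, and adjustment was over all tested lists. For each list, genes past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

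Named genes followed a fixed rule. Genes qualified when they were called changed, had no overlap in CPM between genotypes and reached a mean of at least 2 CPM in the higher genotype. Predicted genes, ribosomal RNA and pseudogenes were left out. The 10 with the largest positive and the 10 with the most negative log2 fold change were taken from the 1420 genes that met these conditions. Up to 4 members of each list with the smallest p, and genes fixed by name, were added, the latter including Ptf1a, Gad1, Gad2, Slc32a1, Slc17a6, Kiss1, Tac2, Pomc, Npy, Sst, Ghrh, Esr1 and Pgr. Some genes that the rule takes are not reported here, without replacement, and still enter the counts of genes and lists. Any other gene named was chosen after its values were seen, and the text says so.

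A dependence of the libraries on transcript GC content was found when the values were examined, and a correction for it was added at that point. Transcript GC content came from GENCODE release M21 (GRCm38), in which 51633 of the gene identifiers were found and 48626 (94.2%) had identical coordinates. For each library, the log2 deviation of each gene from its mean was fitted on GC content by loess (span 0.5), and the fitted values entered edgeR as offsets. The correction removes any real genotype difference that follows GC content together with a technical one.

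The tests were tried on simulated data for the genes past the filter, with the group sizes and spread of these libraries. The filter was not applied again to the simulated counts. Without a GC dependence, 60 of 100 genes with a 2-fold change and 82 of 100 with a 4-fold change were found, with 6 false calls among 12257 genes. Simulated changes were placed only in genes above a minimum mean CPM, so these shares may not hold for sparsely read genes. With a simulated GC dependence of the size seen here, the uncorrected test made 353 false calls and the corrected one 7. The simulated spread came from uncorrected libraries and already held GC-linked spread within genotypes, so 353 may be too few. Camera called 0 of 27 lists without a simulated change and called a list shifted by 1.5-fold. Simulated genes were drawn independently, whereas a correlation of 0.379 was estimated for the shifted list, cell cycle, in the real libraries. The trial therefore does not show how camera behaves when genes are correlated.

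Alternatives fixed in advance were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, unique exon reads, reads over the whole gene, a Y-linked covariate, a haemoglobin covariate, a minimum fold of 1.2 in glmTreat and the omission of each library in turn. Alternatives chosen after seeing the data were the GC correction, a GC and exon length correction, a covariate of reads in olfactory and vomeronasal receptor genes, omission of libraries 1 and 2 or of 1, 2 and 9, combinations of these with the GC correction, the GC correction without each library in turn and the authors' expression value. In all, 37 fits across genes were made, the reported one included. Figures and tables of values were made in Python 3.11.15 and R. The RPKM and TPM columns were left out of the tests because the counts behind them were at hand.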

Results

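RNA of Ptf1a-lineage cells from the mouse fetal hypothalamus at embryonic day 14.5 was sequenced in 8 libraries, 4 from Ptf1a cre/+ and 4 from Ptf1a cre/cre animals. Ptf1a encodes a basic helix-loop-helix transcription factor that directs inhibitory neuron fates in the cerebellum, dorsal spinal cord and retina. The labels describe the cells as 4 control and 4 knockout samples. Heterozygous libraries are numbered 1 to 4 and homozygous libraries 9 to 12. Exon reads were 2757889, 2979647, 2502387 and 2823918 in libraries 1, 2, 3 and 4. Libraries 9, 10, 11 and 12 held 3009181, 2571054, 2806706 and 2631675. Between 14617 and 24852 genes had at least 1 exon read per library. The comparison asks which genes differ in this lineage between animals with 1 intact Ptf1a copy and animals with none.

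Ptf1a itself was barely sampled in either genotype. Heterozygous libraries held 1 exon read of Ptf1a (ENSMUSG00000026735, chromosome 2, 19445663 to 19447501) among 11063841, in library 3. Homozygous libraries held 0 of 11018616, which allows up to 0.272 CPM. The level in either genotype lay under the limit of 3 reads, so no fold is given (exact permutation p = 1), and the genotype labels could not be checked from this gene.

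Skor2, Prdm13 and Lhx5, which act downstream of Ptf1a in other tissues, were lower in homozygous cells, and Isl1 was higher. Skor2, a transcriptional corepressor of cerebellar and spinal inhibitory neurons, fell from 22.1 ± 9.09 to 2.06 ± 2.40 CPM (SD, n = 4 per genotype). Its log2 fold change was -3.42 ± 0.58 (SE; edgeR adjusted p = 0.00315), and -4.61 without library 10, which held 5.65 CPM against 0.702 to 1.10 in the other 3 homozygous libraries. Prdm13, a zinc finger factor downstream of Ptf1a in the spinal cord, fell from 15.4 ± 2.41 to 2.39 ± 1.27 CPM, a log2 fold change of -2.67 ± 0.47 (adjusted p = 0.00338). Lhx5, a LIM-homeodomain factor, fell from 67.2 ± 17.8 to 27.4 ± 6.01 CPM (log2 -1.29 ± 0.22, adjusted p = 0.00338). Isl1, a LIM-homeodomain factor of arcuate neurons, rose from 217 ± 39.7 to 498 ± 72.4 CPM (log2 1.2 ± 0.15, adjusted p = 0.000746). For each of these 4 genes, the 4 libraries of one genotype all lay above the 4 of the other. On GRCm38 they lie on chromosome 18, 76856405 to 76900342 (Skor2, ENSMUSG00000091519), chromosome 4, 21677480 to 21685963 (Prdm13, ENSMUSG00000040478), chromosome 5, 120431699 to 120441223 (Lhx5, ENSMUSG00000029595) and chromosome 13, 116298281 to 116309689 (Isl1, ENSMUSG00000042258). All 4 kept their direction and passed in each fit without 1 library and after correction for transcript GC content, where log2 fold changes were -2.86 for Skor2, -2.26 for Prdm13, -0.92 for Lhx5 and 1.06 for Isl1. None of the 4 passed with reads over the whole gene (log2 -1.46, -2.57, -1.84 and 0.54), with the GC correction plus a Y-linked covariate (-2.49, -2.21, -0.83 and 1.03) or with the GC correction without library 2 (-2.66, -2.42, -0.91 and 1.00). GC-corrected calls were also lost for Skor2 without library 11 (log2 -4.02 to -2.62 over the 8 such fits), Prdm13 without 1, 4, 11 or 12 (-2.51 to -2.06) and Lhx5 without any but library 3 (-1.07 to -0.80). Over all alternatives the adjusted p ranged from 3.91e-11 to 0.267 for Skor2, 2.55e-05 to 0.131 for Prdm13, 4.12e-09 to 0.540 for Lhx5 and 1.35e-12 to 0.267 for Isl1.

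**Figure D1:**
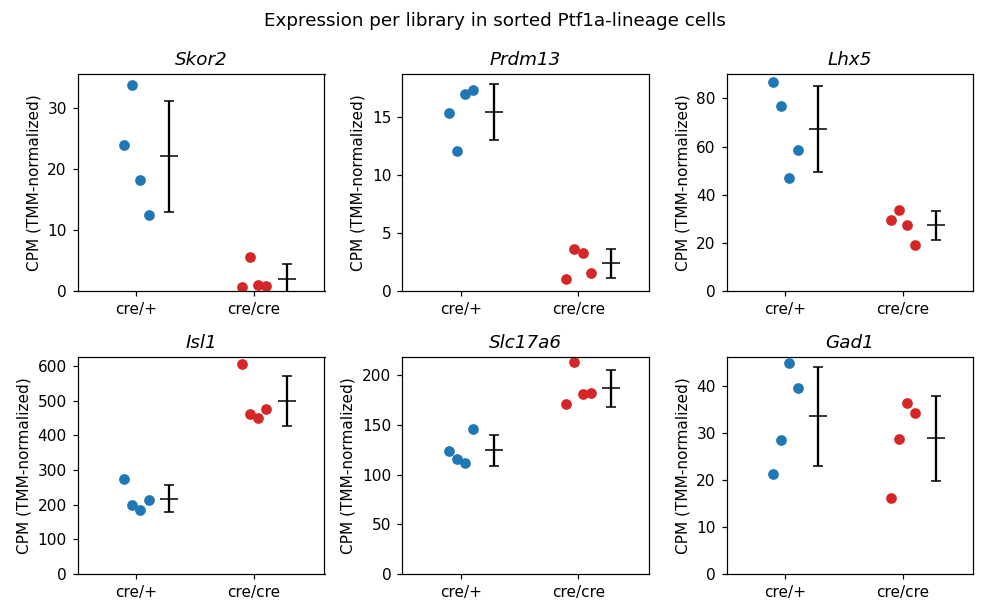
CPM (vertical axes) of 6 genes in the 4 heterozygous and 4 homozygous libraries; each dot is a library, with the mean and SD of each genotype beside the dots. Skor2, Prdm13 and Lhx5 lie lower and Isl1 and Slc17a6 higher in homozygous libraries with no overlap, while Gad1 overlaps between genotypes.

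Skor2, Prdm13 and Lhx5 belong to the list of genes downstream of Ptf1a in other tissues, in which 1 of 10 tested members rose, 3 fell and 6 did not pass (median log2 0.16). Adjusted over the list alone, 3 rose and 3 fell. The riser was Tfap2b, an AP-2 factor of retinal amacrine cells, at 2.48 ± 2.65 and 22.6 ± 25.2 CPM (log2 3.18, adjusted p = 0.0447). Its call was lost after the GC correction (log2 3.28) and without library 1, 2, 4, 10, 11 or 12, with log2 fold changes from 2.09 to 4.04 over the fits without 1 library. Onecut3, chosen after its values were seen, passed only after the GC correction among these 2 fits (log2 0.81 before and 1.18 after). In the PTF1 complex, 1 of 4 tested members rose, 0 fell and 3 did not pass, and 2 rose and 1 fell adjusted over the list alone. That member was Tcf12, an E protein that pairs with Ptf1a (98.6 ± 15.7 and 142 ± 26.1 CPM, log2 0.53, adjusted p = 0.0429). Tcf12 did not pass after the GC correction (log2 0.25) or without library 1, 2, 4, 10, 11 or 12 (log2 0.42 to 0.59 over all fits without 1 library). Rbpjl, the PTF1 subunit of the pancreas, was under the filter, with 7 and 44 reads (exact permutation p = 0.0286, chosen after its values were seen). Background reads, taken from olfactory and vomeronasal receptor genes per kilobase of exon, would make up 0.552 of the rise of Rbpjl between genotype means. Single libraries did not follow this background. It was 0.102 CPM per kilobase in homozygous library 9, with 12 Rbpjl reads. In heterozygous libraries 3 and 4 it was 0.143 and 0.237, with 2 and 4 reads.

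Across all genes, 1603 of 12257 changed, 853 higher and 750 lower in homozygous cells, and 247 changed at least 2-fold (162 higher, 85 lower). At an unadjusted p under 0.05 there were 3597 genes. The genotypes did not overlap for 2404 tested genes (19.6%, against 2.86% by chance). The direction followed transcript GC content: median GC was 44.5% in genes called higher, 56.9% in genes called lower and 50.6% in the other tested genes. When the genes were ranked by GC content in 5 classes of equal size, 500 were called higher and 3 lower in the class with the lowest GC, and 4 and 452 in the class with the highest. The GC slope per library was 0.26 ± 0.22 log2 units per 10 points of GC in heterozygous and -0.26 ± 0.06 in homozygous libraries, without overlap (exact permutation p = 0.0286, adjusted p = 0.105 over 11 measures). After a per-library GC correction, 135 genes were called (66 higher, 69 lower), of which 129 were among the 1603 with the same direction.

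Both counts moved with single libraries. Uncorrected, 985 genes were called without library 1, 734 without 2, 911 without 10, 836 without 11 and 840 without 12. GC-corrected, the counts were 61 without library 1, 23 without 2, 267 without 3, 47 without 10, 41 without 11 and 51 without 12. The balance of directions moved as well, to 559 higher and 1004 lower with a 1 CPM filter and 312 and 118 with a covariate of olfactory and vomeronasal receptor-gene reads chosen after the results were seen. Reads over the whole gene, introns included, gave 6 genes, all lower, and 1 of these was among the 1603.

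**Figure D2:**
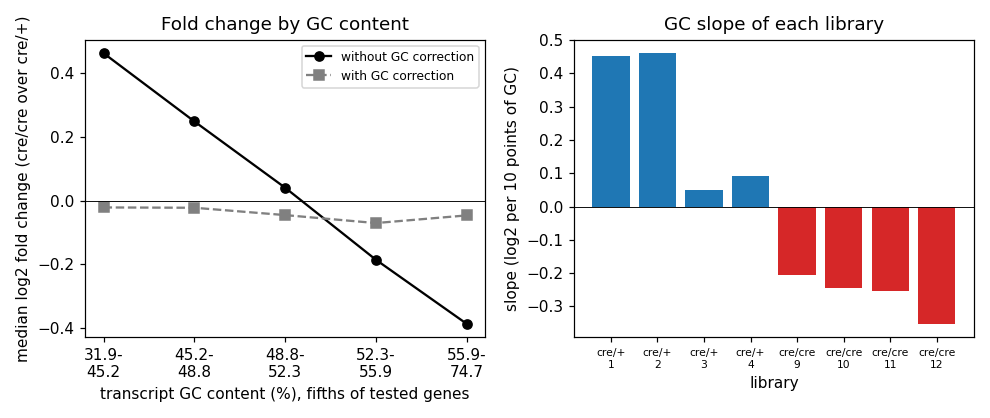
Left, median log2 fold change (homozygous over heterozygous) of the tested genes in 5 classes of transcript GC content, without and with the GC correction; right, GC slope of each library in log2 units per 10 points of GC. Without correction the medians run from 0.46 in the lowest to -0.39 in the highest class, and all 4 homozygous slopes lie below all 4 heterozygous slopes.

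In GABA and glycine transmission, 0 of 7 tested members rose, 1 fell and 6 did not pass (0 and 1 adjusted over the list alone). After the GC correction 0 members passed. Of the 7, 6 were lower in value (median log2 -0.32, -0.33 after the GC correction; limma camera adjusted p = 0.354, limma fry unadjusted p = 0.00406 and adjusted p = 0.0548). The GABA-synthesizing enzyme genes Gad1 (33.5 ± 10.6 and 28.8 ± 9.04 CPM, adjusted p = 0.654) and Gad2 (56.4 ± 24.7 and 48.0 ± 15.1 CPM, adjusted p = 0.641) did not pass. Slc32a1, the vesicular GABA transporter, stood at 21.8 ± 4.05 and 15.4 ± 5.93 CPM (adjusted p = 0.282). Among transcription factors of inhibitory neurons, 0 of 12 rose, 1 fell and 11 did not pass, with the same counts adjusted over the list alone. Camera called this list, down, only without a low-count filter (adjusted p = 0.0330, against 0.354 with it). The homeobox gene Dlx2 fell from 56.0 ± 9.39 to 27.7 ± 11.6 CPM (log2 -1.01 ± 0.25, adjusted p = 0.0171). Its call was lost after the GC correction (log2 -0.64) and without library 2, 10 or 12 (log2 -1.35 to -0.87 over all fits without 1 library).

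In glutamate transmission, 1 of 3 tested members rose, 0 fell and 2 did not pass (1 and 0 adjusted over the list alone). Slc17a6, the vesicular glutamate transporter VGLUT2, rose from 124 ± 15.3 to 187 ± 18.5 CPM (log2 0.59 ± 0.13, adjusted p = 0.0107). It did not pass after the GC correction (log2 0.35), and its direction turned with reads over the whole gene (log2 -0.03). Transcription factors of excitatory neurons had 0 of 12 tested members past the threshold, over all genes or adjusted over the list alone. Nhlh2, a helix-loop-helix factor, stood at 68.4 ± 10.5 and 79.7 ± 16.2 CPM (adjusted p = 0.410).

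Transcription factors that pattern the hypothalamus changed in both directions. Of 28 tested members, 1 rose, 4 fell and 23 did not pass, and 2 rose and 5 fell adjusted over the list alone. Isl1 was the one that rose. Sox3, a SoxB1 factor of hypothalamic and pituitary development, fell from 57.6 ± 7.14 to 22.2 ± 6.21 CPM (log2 -1.37 ± 0.22, adjusted p = 0.00205). Nkx2-1, required for ventral hypothalamic identity, fell from 281 ± 32.4 to 180 ± 34.3 CPM (log2 -0.64 ± 0.15, adjusted p = 0.0137). The paired homeobox genes Hmx2 (95.9 ± 21.9 to 54.6 ± 11.8 CPM, log2 -0.81) and Hmx3 (66.6 ± 14.9 to 35.8 ± 11.5 CPM, log2 -0.90, chosen after its values were seen) fell as well. After the GC correction Isl1 alone of these 5 passed, with log2 fold changes of -0.75 for Sox3, -0.40 for Nkx2-1, -0.60 for Hmx2 and -0.26 for Hmx3. Hmx2 also did not pass without library 10 (log2 -0.99 to -0.69 over the fits without 1 library).

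Neuropeptide and hormone genes showed no change that passed. Of hypothalamic neuropeptides, 7 of 31 were tested and 0 passed, over all genes or adjusted over the list alone. Pomc stood at 63.3 ± 18.3 and 52.9 ± 21.2 CPM (adjusted p = 0.585), Sst at 50.1 ± 8.21 and 50.8 ± 15.0 CPM (adjusted p = 0.962) and Npy at 7.19 ± 4.45 and 6.39 ± 1.47 CPM (adjusted p = 0.872). Under the filter, Kiss1 had 9 and 4 reads (exact permutation p = 0.314), Tac2 1 and 4 (exact p = 0.143) and Ghrh 12 and 13 (exact p = 0.657), so a difference in these was not detectable at this depth. Monoamine neuron genes had 0 of 5 past the threshold on either adjustment, among them Th, which makes dopamine's precursor (20.1 ± 5.02 and 14.9 ± 4.11 CPM, adjusted p = 0.337). Sex steroid and reproductive signalling had 0 of 10 on either adjustment. The estrogen receptor gene Esr1 stood at 3.18 ± 1.42 and 4.89 ± 3.96 CPM (adjusted p = 0.674) and the progesterone receptor gene Pgr at 6.18 ± 1.72 and 8.64 ± 2.99 CPM (adjusted p = 0.515).

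Several genes of differentiated neurons were higher in homozygous cells. Of 19 pan-neuronal genes, 6 rose, 1 fell and 12 did not pass, and 7 rose and 1 fell adjusted over the list alone. Snap25, a synaptic vesicle fusion protein, rose from 70.2 ± 10.6 to 142 ± 31.5 CPM (log2 1.02 ± 0.17, adjusted p = 0.00280). Elavl3, a neuronal RNA-binding protein, rose from 535 ± 49.4 to 780 ± 55.6 CPM (log2 0.54 ± 0.12, adjusted p = 0.00958). Its relative Elavl4 (log2 0.69, adjusted p = 0.00678) and the calcium sensor Syt1 (log2 0.56, adjusted p = 0.00959) rose too, while the neuronal tubulin gene Tubb3 fell (log2 -0.59, adjusted p = 0.0184, chosen after its values were seen). The GC correction left 2 of the 6 risers, Elavl3 (log2 0.76, lost without library 1, 2, 4, 10 or 11, at 0.64 to 0.79) and the RNA-binding protein gene Celf4 (log2 0.52 before and 0.67 after, chosen after its values were seen). It ended the calls of Snap25 (log2 0.65), Elavl4 (0.12), Syt1 (0.15) and Tubb3 (-0.26). With reads over the whole gene the direction turned for Elavl3 (log2 -0.12), Elavl4 (-0.03) and Syt1 (-0.13).

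Of 26 synaptic receptors and channels, 1 rose, 1 fell and 24 did not pass (1 and 0 adjusted over the list alone). Cacna1a, a calcium channel subunit, fell by 0.49 on the log2 scale (adjusted p = 0.0490), a call lost after the GC correction and without each of the 8 libraries (log2 -0.57 to -0.41). In axon guidance, 1 of 30 rose, 3 fell and 26 did not pass, with the same counts adjusted over the list alone. The Slit receptor gene Robo2 rose (log2 0.61, adjusted p = 0.0184), and the netrin receptor gene Unc5a (-0.80, adjusted p = 0.0442), Slit1 (-0.56, adjusted p = 0.0442) and Efnb3 (-0.62, adjusted p = 0.0128) fell. All 4 calls were lost after the GC correction (log2 0.23, -0.34, -0.21 and -0.32). Calls were also lost for Robo2 without library 1, 2, 9 or 10 (log2 0.43 to 0.72), Unc5a without 1, 2, 4, 9, 10 or 12 (-1.08 to -0.63), Slit1 without 1, 2, 11 or 12 (-0.70 to -0.45) and Efnb3 without 11 (-0.75 to -0.53).

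Progenitor and signalling lists held few calls. Of 17 neural progenitor genes, 0 rose, 1 fell (Sox3) and 16 did not pass, with the same counts adjusted over the list alone. Vim, an intermediate filament gene of progenitors, stood at 275 ± 43.4 and 369 ± 80.0 CPM (adjusted p = 0.101). Of 18 cell cycle genes, 1 rose and 17 did not pass, with the same counts adjusted over the list alone. Tpx2, a spindle assembly factor, rose from 6.17 ± 2.98 to 16.7 ± 3.64 CPM (log2 1.42, adjusted p = 0.0294), a call lost after the GC correction (log2 1.30) and without library 1, 2, 10, 11 or 12 (log2 1.22 to 1.76). In Notch signalling, 1 of 14 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone. Mib1, a ubiquitin ligase for Notch ligands, rose (log2 0.64, adjusted p = 0.0112), and the ligand gene Jag2 fell (log2 -0.62, adjusted p = 0.0477). Neither passed after the GC correction (log2 0.35 and -0.20), and Jag2 did not pass without library 1, 2, 4, 9, 11 or 12 (log2 -0.76 to -0.54). Sonic hedgehog and Wnt signalling had 0 of 17 past the threshold on either adjustment. Apoptosis and p53 genes had 0 of 11 over all genes, and 1 rose and 2 fell adjusted over the list alone. Bax, a cell death effector, stood at 41.8 ± 5.30 and 27.2 ± 6.60 CPM (adjusted p = 0.0682).

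Of 14 immediate-early and dissociation genes, 1 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. The chaperone gene Hsp90aa1 rose from 610 ± 139 to 1680 ± 104 CPM (log2 1.46 ± 0.15, adjusted p = 0.000306) and was called in each fit without 1 library, with and without the GC correction (log2 1.21 with it). Dusp1, a phosphatase of MAP kinases, fell from 51.8 ± 4.79 to 27.6 ± 2.25 CPM (log2 -0.91 ± 0.17, adjusted p = 0.00474) and passed after the GC correction (log2 -0.84), though not without library 1, 2, 4, 10, 11 or 12 (-0.93 to -0.80). Egr1 (log2 -1.38, adjusted p = 0.0231), Jund (log2 -0.88, adjusted p = 0.00170) and Jun (log2 -0.56, adjusted p = 0.0378, chosen after its values were seen) fell, and none of these 3 passed after the GC correction (log2 -1.18, -0.21 and -0.35). Egr1 did not pass without library 1, 2 or 12 (log2 -1.59 to -1.08).

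Markers of other cells and regions were measured in the same libraries. Of 7 astrocyte and tanycyte genes 1 rose, of 4 oligodendrocyte lineage genes 1 rose and of 7 telencephalon genes 1 rose, with 0 falls and the same counts adjusted over each list alone. Bcl11b, a zinc finger factor also called Ctip2, rose from 115 ± 16.4 to 201 ± 38.5 CPM (log2 0.81 ± 0.16, adjusted p = 0.00557). Col23a1, a collagen gene of tanycytes, rose from 3.63 ± 1.45 to 13.3 ± 3.29 CPM (log2 1.87 ± 0.44, adjusted p = 0.0137), which did not pass without library 12 (log2 1.69 to 2.13). Both genes also passed after the GC correction (log2 1.16 and 2.11), Bcl11b also in each such fit without 1 library, while Col23a1 (1.92 to 2.39) was then called only without library 3. No member passed, over all genes or adjusted over the list alone, among 5 endothelial, 7 mesenchymal and pericyte, 5 erythroid, 11 thalamus and prethalamus or 4 Y-linked genes. Of the 13 erythroid genes, 10 were in the tables. None of the 15 myeloid, 12 pituitary, 20 hindbrain and spinal cord or 11 retina and eye genes was past the low-count filter. All 7 tested astrocyte and tanycyte genes and all 7 mesenchymal and pericyte genes had higher values in homozygous cells (median log2 0.37 and 1.25), but camera did not call these lists (adjusted p = 0.514 and 0.354). Homozygous library 12 carried much of this, with 156 reads of Gja1 against 0 to 26 and 86 of Col1a2 against 3 to 45 in the other 3 homozygous libraries. Without it the medians of tested members were -0.50 and 0.31. Haemoglobin reads per 1000000 exon reads were 0 to 96.3 in heterozygous and 0.665 to 85.5 in homozygous libraries (exact permutation p = 0.6).

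The genes with the largest rises, among genes without overlap between genotypes, predicted and uncharacterised genes left out, were sparsely read. Muc19, a gel-forming mucin, rose from 1.43 ± 1.59 to 17.4 ± 10.3 CPM (log2 3.56 ± 0.75, adjusted p = 0.00817). It was followed by Tmcc3os (log2 3.11), Slc43a1 (3.0), Itgb3 (2.80), Myo5c (2.73), H2-Q7 (2.68), Slc16a10 (2.57), Fmn1 (2.52), Rgs9bp (2.49) and Fgf2 (2.38), with adjusted p from 0.00919 to 0.0449. Tmcc3os is annotated as antisense and H2-Q7 shares sequence with other class I histocompatibility genes, so their counts are uncertain. Muc19, Myo5c, H2-Q7 and Fmn1 also passed after the GC correction (log2 3.46, 2.53, 2.87 and 2.29), and the other 6 did not, though their folds stayed near the uncorrected ones (Tmcc3os 3.02, Slc43a1 3.12, Itgb3 2.79, Slc16a10 2.51, Rgs9bp 2.27 and Fgf2 2.21). With that correction calls were lost for Muc19 without library 2, 10 or 11 (log2 3.05 to 4.33), Myo5c without any but 9 (2.22 to 2.83), H2-Q7 without 2, 10, 11 or 12 (2.46 to 3.14) and Fmn1 without 1, 2, 10, 11 or 12 (2.00 to 2.74). Uncorrected, Muc19 was called in all 8 fits without 1 library. Calls were lost for Myo5c (log2 2.42 to 3.12), H2-Q7 (2.31 to 2.97) and Fmn1 (2.23 to 3.05) without library 11. The losses were without 1, 2, 4, 10 or 11 for Tmcc3os (2.88 to 3.63), any but 4 for Slc43a1 (2.58 to 4.06), 1, 2, 10, 11 or 12 for Itgb3 (2.41 to 3.31), 1, 2, 3, 10, 11 or 12 for Slc16a10 (2.17 to 3.45), any library for Rgs9bp (2.05 to 2.95) and any but 3 or 4 for Fgf2 (1.98 to 2.98). Reads in olfactory and vomeronasal receptor genes, which these cells are not known to express, were 471 ± 467 per 1000000 exon reads in heterozygous and 1868 ± 1002 in homozygous libraries (exact permutation p = 0.0857, adjusted p = 0.189). Reads at that level per kilobase of exon would make up 0.132 (H2-Q7) to 0.473 (Rgs9bp) of the rises of these 10 genes.

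Among genes without overlap between genotypes, predicted and uncharacterised genes left out, the most negative changes after Skor2 and Prdm13 were in Nup62cl, a nucleoporin-like gene on chromosome X (log2 -2.29 ± 0.35, adjusted p = 0.00188), and Tuba1c, an alpha-tubulin gene (-2.28 ± 0.63, adjusted p = 0.0300). Rhpn1 (-2.22), the ribosomal protein gene Rps27 (-2.11), Doc2a (-2.02), the copper chaperone gene Atox1 (-1.89), Tmem38b, an intracellular cation channel gene (-1.67), and Dxo (-1.62) followed, with adjusted p from 0.00140 to 0.0474. Rps27 fell from 68.2 ± 22.8 to 15.7 ± 6.29 CPM and Tmem38b from 153 ± 52.3 to 48.3 ± 23.0 CPM. Nup62cl, Rps27 and Tmem38b were called in each fit without 1 library, with and without the GC correction, while Tuba1c, Rhpn1, Doc2a, Atox1 and Dxo did not pass with it (log2 -2.17, -1.79, -1.47, -1.49 and -1.28). Tuba1c, which shares sequence with other tubulin genes, had 258 CPM in library 1, and without that library its log2 fold change was -0.87 and did not pass. Its call was also lost without 9, 10, 11 or 12, and its direction turned with the receptor-gene covariate (log2 0.09). Calls were lost without 1, 9, 10, 11 or 12 for Doc2a (log2 -2.35 to -1.65), 1, 2, 9, 11 or 12 for Atox1 (-2.33 to -1.40) and 1, 2 or 10 for Dxo (-2.02 to -1.34). Doc2a was tested in 6 of the 8 fits without 1 library, and 5 of these lost its call.

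No gene list moved together. Camera called 0 of 27 tested lists, 3 at an unadjusted p under 0.05, with pan-neuronal genes lowest (up, adjusted p = 0.243), then Notch signalling and immediate-early and dissociation genes (down, adjusted p = 0.268 each). With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05, and fry called 0 with 4 at an unadjusted p under 0.05. After the GC correction camera again called 0. Median, mean and test differed in sign for genes downstream of Ptf1a (median 0.16, mean -0.17, test down), regional hypothalamic transcription factors (0.01, -0.08, down), neural progenitors (0.24, 0.02, down), axon guidance (0.05, 0.05, down) and thalamus and prethalamus genes (-0.08, 0.02, up).

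Whole profiles were compared between libraries. Spearman correlations of log2 CPM across genes were 0.926 to 0.962 within heterozygous, 0.936 to 0.956 within homozygous and 0.884 to 0.955 between genotypes; genes are not independent replicates. Distances between genotypes exceeded those within by 0.0224 (exact permutation p = 0.0286, the smallest possible), and by 0.0104 after the GC correction (exact p = 0.0571). The first principal component held 43.0% of the variance and did not part the genotypes, with libraries 1 and 2 at -75.1 and -47.9, libraries 3 and 4 at 9.81 and 2.21 and homozygous library 9 at -2.97. Mitochondrial genes took 1.06 ± 0.207% of exon reads in heterozygous and 2.12 ± 0.427% in homozygous libraries (exact p = 0.0286, adjusted p = 0.105 over 11 measures). Among measures chosen after the results were seen, the predicted gene Gm10800 took 2209 and 10132 reads per 1000000 exon reads (exact p = 0.0286, adjusted p = 0.105) and Lars2 21545 and 9973 (exact p = 0.0571, adjusted p = 0.157). Total exon reads (exact p = 0.943), genes detected (18746 ± 3548 and 22350 ± 3211, exact p = 0.171) and the share of the 10 most counted genes (6.09 and 5.89%, exact p = 0.686) did not pass the exact test. Libraries 1, 2, 3 and 10 carried the bulk of the Y-linked reads and at most 13 reads of Xist, the X-inactivation transcript, and libraries 4, 9, 11 and 12 at least 2503 Xist reads, so the sexes, which the labels do not give, were uneven between genotypes.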

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

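No tests in this part were chosen after the results were seen. In each genotype, the highest or lowest of the 4 libraries was compared with the other 3 by Dixon's ratio at the 95% level for every named gene and 5 measures of library quality. A library stood apart in 20 of 257 such groups, where independent normal values would give about 1 in 20, or 12.8. These groups do not meet that condition, so 12.8 is only a rough guide. Many named genes were taken by rule for their values in these libraries, and the Y-linked genes vary together. A gene with 1 read in 1 library and 0 in the others, as Ptf1a and Tac2 in heterozygotes, stands apart by construction. All values are CPM.

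The Y-linked genes stood apart in homozygous library 10, with 29.9 for Eif2s3y, 25.0 for Ddx3y, 93.7 for Kdm5d and 44.4 for Uty, against at most 1.40 in libraries 9, 11 and 12. Library 10 also had the highest Skor2 level among homozygous libraries, 5.65 against 0.702 to 1.10.

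Homozygous library 12 stood apart in genes of glia and blood vessels. Gja1, a gap junction gene, was 61.2 there and 0 to 9.53 in the other homozygous libraries, the matrix gene Tnc 41.2 against 4.91 to 6.86, and the endothelial receptor gene Kdr 72.2 against 3.51 to 9.90. Kdr also stood apart in heterozygous library 3, at 50.5 against 0 to 4.50.

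Heterozygous library 3 stood apart in several further genes. Alas2, an enzyme of haem synthesis, was 13.1 against 3.46 to 4.68, Cacna1a 141 against 101 to 106, Col23a1 5.78 against 2.61 to 3.11, and Tmcc3os 1.16 against 0.334 to 0.373. The single Ptf1a read gave 0.385 in library 3 against 0 in libraries 1, 2 and 4.

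Single genes stood apart in other libraries. Tuba1c was 258 in heterozygous library 1 against 21.6 to 54.8, and 19.8 in homozygous library 11 against 17.8 to 18.1. Unc5a was 93.6 in library 2 against 61.7 to 65.0. Rhpn1 was lowest in library 4 at 9.34 against 11.6 to 11.9, where 1 read of Tac2 gave 0.346 against 0. Abat, which breaks down GABA, was 131 in library 11 against 115 to 117.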

How the results depend on the processing

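Tests with a GC correction, a GC and length correction, the receptor-gene covariate, libraries 1 and 2 or 1, 2 and 9 left out, or the authors' expression value were chosen only after the results were seen. The count of 1603 changed genes stayed within 1.5 times under RLE, upper-quartile normalization, DESeq2, limma-voom, no filter, the 1 CPM filter, unique exon reads and the authors' expression value (1563 to 2147). It was 6 with reads over the whole gene, 477 with the Y-linked covariate, 2426 with the haemoglobin covariate, 533 for a fold of at least 1.2 and 734 to 2077 without 1 library, lowest without library 2 and highest without library 3. Chosen later, the GC correction gave 135, GC and length 134, the receptor-gene covariate 430, GC with that covariate 215, libraries 1 and 2 left out 474, libraries 1, 2 and 9 left out 746, GC with 1 and 2 left out 28 and GC with the Y-linked covariate 12. GC correction gave 61, 23, 267 and 108 without libraries 1, 2, 3 and 4, and 147, 47, 41 and 51 without 9, 10, 11 and 12. The cause of each shift was not tested, except that fewer libraries or an added covariate leave fewer degrees of freedom and a minimum fold is a stricter test. Without a filter the median log2 fold change of all genes was 0.38, against 0.04, and 782 genes were higher and 1365 lower. The split was 559 and 1004 with the 1 CPM filter, 312 and 118 with the receptor-gene covariate and 172 and 43 with GC added to it.

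Lists called moved from 0 to 1 with limma-voom (pan-neuronal genes, up), 4 without a filter (transcription factors of inhibitory neurons, Notch signalling and immediate-early and dissociation genes, down; hindbrain and spinal cord genes, up), 2 with reads over the whole gene (regional hypothalamic transcription factors and immediate-early and dissociation genes, down), 3 with the receptor-gene covariate (pan-neuronal genes, up; Notch signalling and erythroid genes, down), 2 with GC and that covariate (pan-neuronal genes, up; erythroid genes, down) and 2 with GC and libraries 1 and 2 left out (synaptic receptors and channels and erythroid genes, down). With the GC correction 3, 2, 5 and 2 lists were called without libraries 3, 4, 9 and 10, and 0 without 1, 2, 11 or 12. These were Sonic hedgehog and Wnt signalling and astrocyte and tanycyte genes (up without 3 or 9), mesenchymal and pericyte genes (up without 3, 4 or 9), cell cycle and myeloid genes (up without 9), pan-neuronal genes (up without 10) and Y-linked genes (down without 4 or 10). Camera with an estimated correlation, and each uncorrected fit without 1 library, called 0. The synaptic receptor list turned to a median of -0.26 with GC and libraries 1 and 2 left out (adjusted p = 0.0172). The causes were not tested.

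Reads over the whole gene turned Slc17a6 (-0.029), Elavl4 (-0.032), Elavl3 (-0.12) and Syt1 (-0.13). Tuba1c turned with the receptor-gene covariate (0.088) and with GC plus that covariate (0.25). GC correction without library 3 turned Elavl4 (-0.041), and without library 9 it turned Syt1 (-0.0044) and Robo2 (-0.019). All are log2 fold changes whose cause was not tested. Among 120 named genes with a fit, 120 kept direction and call under RLE, 89 under the GC correction with 31 calls lost, and 72 with reads over the whole gene with 43 lost. Of 47 named genes called, 21 were called in each fit without 1 library and 16 after the GC correction. Of these 16, 5 were also called in each GC-corrected fit without 1 library (Nup62cl, Rps27, Tmem38b, Hsp90aa1 and Bcl11b). Each of the 5 still missed the threshold in some alternative. Their highest adjusted p over all alternatives were 0.143, 0.0878, 0.0807, 0.108 and 0.538 in that order, and the lowest log2 fold change of Bcl11b was 0.19. Another 409 changes of sign were between values that both missed the threshold, and 47 named genes had no adjusted p in DESeq2. Of all genes, 404 were called in every alternative fixed in advance except glmTreat and reads over the whole gene (242 higher, 162 lower). Of these 404, 80 passed after the GC correction. Once reads over the whole gene were included, 0 genes were called in every such alternative. The main fit and every fit with a GC correction shared 9 called genes, 4 of them higher.

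Separation of the genotypes was 0.0171 to 0.0282 without 1 library, 0.0252 with Pearson correlation and 0.140 on the 500 most variable genes (each exact p = 0.0286), but 0.0104 after the GC correction (exact p = 0.0571). Ptf1a had 0.25 reads per heterozygous library, 0.25 with reads over the whole gene, 0 with unique exon reads and 0 to 0.333 without 1 library (0 without library 3). Normalization, test, filter and covariate do not change a raw read count and were not run for it. No paired analysis was possible because libraries 1 to 4 and 9 to 12 share no number. Alternatives of the pseudocount and of a filter on normalized values were not run because the tables held counts. Depth limits genes such as Kiss1, Tac2 and Ghrh, with at most 13 reads per genotype.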

Other observations

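Tests of GC content, of unequal sexes, of ribosomal protein genes and of the gene families here were chosen only after the results were seen. For genomic DNA, the region near Ptf1a and other splits, the rules were written before those tests were run. Some of these rules still concern patterns known only from the results, such as Skor2 and Prdm13 reads left in homozygotes. The receptor-gene reads and the GC correction that some of them use were also chosen after the results were seen.

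The gene families here were chosen after their values were seen, so their counts are not independent evidence. Of 62 chaperone genes, 16 rose and 0 fell, 5 of the 16 also after the GC correction, among them Hsp90b1 (log2 1.14), an endoplasmic reticulum chaperone, and Hspd1 (0.73), a mitochondrial one. Of 14 host genes of small nucleolar RNAs, which guide ribosomal RNA modification, 0 rose and 7 fell (6 also after it), with Snhg1 at -0.82, Snhg20 at -1.41 and Gas5 at -0.59. Of 56 replication-dependent histone genes, 0 rose and 10 fell (6 also after it), including Hist1h4d (-1.15). These directions are medians of 0.27, -0.68 and -0.53, with adjusted p = 0.0792 each in camera with an estimated correlation. With uniquely mapped reads the medians were 0.21, -0.43 and -0.54. After the GC correction the medians were 0.09, -1.02 and -0.44. Library medians then differed by 0.05 (exact p = 0.657), -0.66 (exact p = 0.0571) and -0.33 (exact p = 0.0857), and histone genes, with a median exon length of 486.5 against 4437 bases, by -0.17 (exact p = 0.314) once length was corrected as well. Histone genes share sequence with one another, so counts of single members are uncertain.

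Other genes, chosen after their values were seen, passed both with and without the GC correction. Magel2, an imprinted gene of the hypothalamus, fell (log2 -1.02 without and -0.72 with the correction), as did the imprinted gene Mest (-0.82 and -0.87) and Zcchc12, a zinc finger gene (-0.77 and -0.97). Sox21, a SoxB2 factor, rose (0.56 and 0.89), as did the chromatin remodelling genes Smarca1 (1.28 and 0.92) and Smarca2 (1.03 and 0.75), topoisomerase Top1 (1.40 and 0.92) and nucleolin, Ncl (1.18 and 0.89).

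The first pattern weighed is the set of 1603 changed genes, whose direction followed GC content. Only 6 genes were called with reads over the whole gene, of which introns took a mean of 67.2% in heterozygous and 66.2% in homozygous libraries. With the GC correction and the Y-linked covariate together, 12 were called. Genomic DNA is argued against, since the rise expected from receptor-gene reads per kilobase was 0.0394 of the observed rise for the median gene called higher and 0.0363 for those at least 2-fold higher, though 0.132 to 0.473 in the 10 sparsely read genes named for the largest rises, where a part from DNA stays open; a covariate of these reads left 430 calls (312 higher, 118 lower). Unequal sexes are argued against as the whole cause, since a Y-linked covariate left 0.933 of the median change (log2 0.70 to 0.65, median SE 0.16 to 0.18), though the count fell to 477. Chance is argued against but not excluded: 1 of 35 splits of the libraries, the real one, gave as many genes, the highest other giving 6. The same held after the GC correction (1 of 35, 135 genes, highest other 10). The 35 splits allow no p below 0.0286, and any difference between libraries that runs with genotype would give the same result. A GC-linked technical difference between libraries stays open and may account for an unknown share of the calls, since 129 of 1603 were left after its correction. A simulated dependence of this size made 353 false calls without the correction. That simulation took its spread from uncorrected libraries, so 353 may be too few and does not bound the share. The slopes part by genotype, so a real effect that follows GC is not separated from a technical one.

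For gene lists the real split called 0, so all 35 of 35 splits gave at least as many whatever their cause, and there is no list call for chance to explain. The highest other split called 13, with a median of 2.

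The second pattern is the lower level of Skor2, Prdm13 and Lhx5 with a higher level of Isl1. GC content bias is argued against as the whole cause in these 4 genes only, since at least 0.712 of each log2 fold change was left after its correction. All 4 passed after it, but they were grouped after the results were seen, so this is not independent evidence. Other transcription factor genes lost their calls with the correction, such as Sox3 (log2 -1.37 before and -0.75 after) and Dlx2 (-1.01 before and -0.64 after). Unequal sexes are argued against likewise, since at least 0.886 was left with the Y-linked covariate. In libraries with Xist, 1 heterozygous and 3 homozygous, CPM were 12.5 and 0.862 for Skor2, 17.3 and 1.97 for Prdm13, 58.5 and 25.4 for Lhx5 and 213 and 510 for Isl1. A single heterozygous library gives no spread, so these values are no test. Reads left in homozygotes may be genomic DNA, which would give 1.40 CPM for Skor2 and 1.91 for Prdm13 against 2.06 and 2.39 observed (lowest ratio 0.681; without library 10 the ratios were 1.38 and 0.822), and a low level of transcript cannot be told apart from it. The receptor genes behind this estimate have a median GC content of 40.5%, against 64.3% for Skor2 and 60.7% for Prdm13. Homozygous libraries held relatively fewer reads of GC-rich genes, so the expected levels may be too high. Counts of pooled cells do not separate a change within cells from a change in the mix of sorted cells, and none of the 4 passed with GC correction and covariate together or with GC correction without library 2.

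The third pattern is the lower level of ribosomal protein genes, of which 2 of 77 rose and 26 fell (median log2 -0.33; adjusted p = 1.6e-08 in camera, adjusted p = 0.243 with an estimated correlation). Reads shared with pseudogenes are argued against, since the median with uniquely mapped reads was -0.362 and library medians differed by -0.377 (SE 0.11, exact p = 0.0286). Shorter transcripts recovered less well may contribute, since the median was -0.187 after the GC and length correction and library medians differed by -0.108 (SE 0.109, exact p = 0.371); ribosomal protein genes have a median exon length of 1739 against 4437 bases in all tested genes. The GC correction left a median of -0.305, so most of the shift in the median stayed. Camera then gave adjusted p = 4.36e-09 at the preset inter-gene correlation of 0.01. A correlation of 0.467 was estimated for this family before the correction, and the family was chosen after its values were seen. That p is therefore no support, and camera with an estimated correlation was not run on this family after the correction. GC content bias is still not excluded, since library medians differed by -0.245 (SE 0.091, exact p = 0.0571) before and -0.226 (SE 0.139, exact p = 0.143) after it, neither past the threshold.

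A strain segment carried along with the targeted allele could change genes near Ptf1a. Within 10 Mb of it on chromosome 2, 14 of 121 tested genes were called (11.6%, against 13.1% elsewhere, Fisher's exact p = 0.786), a ratio of 0.884. This argues against a segment that raises the share of calls nearby. A segment that changes a few genes would not be seen by such a test and is not excluded. Of the 14 genes, 1 also passed after the GC correction.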
